A study of Mus musculus with 2 samples.

How the data were processed

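USF1, a basic helix-loop-helix leucine zipper transcription factor, was measured by ChIP-seq in CH12.LX, a mouse B-cell lymphoma line, in 1 group of 2 biological replicates. Chromatin bound by the USF1 antibody was sequenced, per the labels. The labels point to possible control experiments; control libraries were not used here. The deposited files used here are lists of regions, and read counts per replicate are not given in the sources used here, so sequencing depth is unknown.

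Per the deposited readme files, each replicate has a relaxed list of peaks and background in mm10, and a further relaxed list was made from both replicates together; each came from alignments and 1 file that the readme files do not describe. The authors then derived an optimal and a conservative list from these relaxed lists and another undescribed file. Both were thresholded by IDR, which compares the ranks of regions between lists. Which lists were compared for each is not known here. A separate list in mm9 was derived from both replicates' mm9 alignments, per the same readme files. The peak caller, its threshold and the aligner are not given in the sources used here. The authors' signal value of each region (column 7 of the deposited narrowPeak lists) was used as deposited; its scale is not given, and its highest value was 640 in the mm10 list of both replicates and 7241 in the mm9 list, so signal was compared only within a build. Column 9 of the deposited mm9 list was read as −log10 q. In every deposited mm10 list except that of replicate 2 the same column fell below 0 for some regions, which a −log10 q cannot, so it was read as a score in all of them. Column 5 of the deposited thresholded lists was also read as a score and not used further; ties in signal were broken by column 9 and then by position. The summit was taken as the region's start plus the offset in column 10. All coordinates are 1-based, in the build named, and none was converted between builds.

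An mm10 region counted as shared with another list at an overlap of at least 1 bp. The chance level came from 1000 circular shifts of all regions along each chromosome, which keep the spacing of regions and so are not independent placements. Replicate signal was compared by Spearman's rho across optimal regions found in both replicates, with an interval from Fisher's z transformation; regions are not independent replicates, so no p is given. Transcription start sites (TSSs) in mm10 came from the RefSeq annotation of GRCm38.p6, with a single 5′ end per protein-coding gene. That annotation gave no strand, so strand was taken from Gencode vM1 by gene symbol or synonym and chromosome, for 20579 of 21883 genes (94.0%); the other genes were left out of TSS results. A summit within 1 kb of a TSS was called proximal and any other distal. Random positions were drawn in the same number per chromosome between 3 Mb and the end of the last deposited region.

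No mm10 sequence was used here, so every sequence result rests on the mm9 list of 10624 peaks, the NCBIM37 genome and the TSS of every protein-coding transcript of Gencode vM1. The plan fixed before the data were examined had named the optimal list for these results. Windows of 50 bp on each side of the summit (101 bp) were searched on both strands, against windows centred 500 bp upstream and downstream of the same summits. The E-box share was tested by an exact McNemar test against the upstream window, the trend over 5 equal bins of signal by 100000 permutations, and other shares by Fisher's exact test. For hexamers and motif strings Fisher's test treated summit and control windows as independent, though both come from the same peaks. For flanking bases, the CACGTG copy nearest the summit was set against copies 250 to 1000 bp away. All 2080 hexamers, merged with their reverse complements, were ranked by the log2 ratio of their window shares with a pseudocount of 1 window. A further 20 motif strings were fixed before the data were examined.

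A gene was called bound when an optimal summit lay within 1 kb of its TSS. Each of 21 gene lists, written before the data were examined, was tested by Fisher's exact test against all other protein-coding genes with a strand on chromosomes that carry peaks; 634 of 636 list entries were matched, and Hmgcs1 and Rpl41 were not. Each list was also set against 10000 random lists matched on the decile of promoter CpG observed over expected within 500 bp of the TSS. No list was matched on expression or open chromatin. All tests were two-sided, p values were adjusted by the Benjamini-Hochberg method within each family, and the threshold was 0.05. Intervals of shares are 95% Wilson intervals and cover counting error only. A p that the software returned as 0 is stated as 0 at machine precision.

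Named genes followed a rule fixed before the data were examined. It takes the 25 genes with the strongest optimal summit within 1 kb of their TSS and the 10 strongest distal optimal summits with their nearest gene. From each gene list it takes the count bound and up to 4 bound members by signal, and all members of the bHLH-ZIP list; some genes that the rule takes are not reported here. The settings varied by plan were the conservative list, each replicate alone, other overlaps, other distances to the TSS, other windows and controls, CpG-matched lists and shuffled windows. The mm9 annotation, the strongest and weakest 50% of the mm9 list, leaving out chromosomes 3, 11 and 16, all replicate 1 regions found in replicate 2, promoter odds within bins of signal (10000 permutations within bins), and every alternative for the named genes were chosen after seeing the data.

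Scripts were tested on simulated data. Of 50 gene lists with planted binding, 50 were recovered, with 5 false calls among 1050 simulated lists in all; the planted CACGTG ranked 1 among 2080 hexamers, and a planted overlap of 58.3% was returned as 58.3%. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.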

Results

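USF1 binding was mapped in CH12.LX cells, a mouse B-cell lymphoma line from strain B10.H-2aH-4bp/Wts, in 2 biological replicates of 1 group. With no other condition, the comparisons are between the replicates, between lists of different stringency, and between kinds of bound sites. Replicate 1 had 25978 relaxed regions and replicate 2 had 44551, while the relaxed list from both replicates together held 300000. The optimal list held 8108 regions and the conservative list 7356, with a median width of 300 bp in each. The mm9 list held 10624 peaks. The number of reads behind each list is unknown.

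The strongest USF1 sites were found in both replicates. Of the 8108 optimal regions, 8054 (99.3%, interval 99.1 to 99.5) overlapped a region of each replicate, where random shifts gave 0.374% on average. In replicate 1, all of its 2000 strongest regions overlapped a region of replicate 2, and 28.8% of those ranked 22001 to 24000 did. Over the full lists, 62.9% (62.3 to 63.4) of replicate 1 regions were found in replicate 2, and 37.0% (36.6 to 37.4) of replicate 2 regions in replicate 1. The optimal list was derived from these same relaxed lists, so its overlap with them is partly built in. Between the 8108 strongest regions of each replicate, taken without the thresholded lists, 81.6% (80.7 to 82.4) of those of replicate 1 overlapped one of replicate 2.

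**Figure D1:**
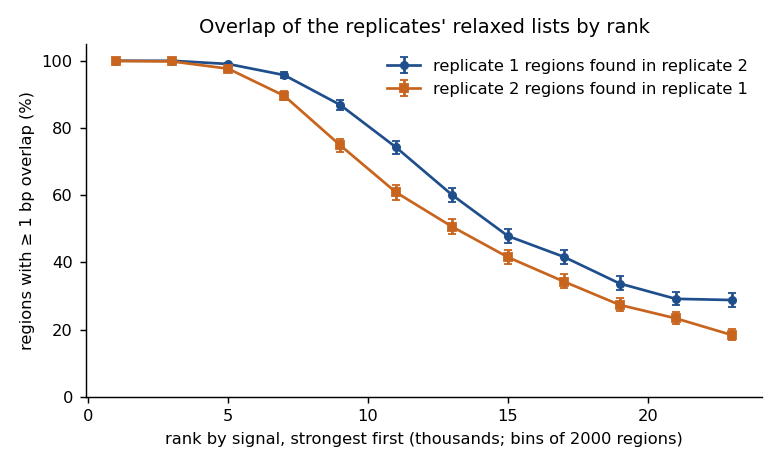
Share of each replicate's relaxed regions that overlapped a region of the other replicate (y axis, percent) by rank of signal in bins of 2000 regions (x axis), with 95% Wilson intervals as bars. Replicate 1 fell from 100% in its strongest bin to 28.8% at ranks 22001 to 24000, and replicate 2 from 99.95% to 18.4%.

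Signal, the authors' own value for each region, followed a similar order in both replicates at the shared sites. Across all 16329 replicate 1 regions that overlapped a replicate 2 region, Spearman's rho was 0.830 (0.825 to 0.835). It was 0.874 (0.869 to 0.879) across 8054 optimal regions found in both. The optimal list was thresholded by IDR, so this value may be partly built in. Whether ranks between the 2 replicates decided that list is not known here. In these optimal regions the median log2 ratio of replicate 2 over replicate 1 was 0.18 with an SD of 0.50 across regions. Signal differed by more than 2-fold at 580 regions (7.20%), being higher in replicate 2 at 447 and in replicate 1 at 133. In the conservative list it did so at 139 regions (1.89%), 131 higher in replicate 2 and 8 in replicate 1. That list was also thresholded by IDR. Among the 16329 regions signal differed by more than 2-fold at 1233 (7.55%), 800 higher in replicate 2 and 433 in replicate 1.

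The regions that the conservative and optimal lists shared were stronger than those in the optimal list alone, and their more frequent position at promoters went with that strength. A total of 6786 optimal regions (83.7%, 82.9 to 84.5) overlapped a conservative region, and 1322 did not. Median signal was 88.1 in the shared regions and 36.0 in the others. Proximal summits made up 29.0% of the shared regions and 18.99% of the others, with an odds ratio of 1.74 (Fisher's exact test, p = 2.0e-14). Compared within 5 equal bins of signal, the odds ratio was 0.998 (permutation test, p = 1). This rests on the 3 weaker bins, since the strongest bin held 0 of the others and the next held 2. From stronger to weaker, the proximal shares in those 3 bins were 20.7%, 19.9% and 17.4% of the shared regions and 11.8%, 18.1% and 19.6% of the others. The conservative list was not a subset of the optimal list, since 568 of its regions had no optimal counterpart.

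USF1 was found at gene starts far more often than random positions were. Of 8107 optimal summits on assembled chromosomes, 2217 (27.3%, 26.4 to 28.3) lay within 1 kb of a protein-coding TSS, against 1.47% (1.23 to 1.75) of random positions. The odds ratio was 25.3, and Fisher's exact p was 0 at machine precision. Taken from each replicate's own strongest regions, the proximal share was 27.7% ± 0.584 (SD, n = 2). Strong sites were the most promoter-bound. The proximal share was 53.8% (51.4 to 56.2) in the strongest of 5 equal bins of signal and 18.7% (16.9 to 20.7) in the weakest. Median signal was 121 at proximal and 65.2 at distal summits. Of the 5890 distal summits, 53.4% lay inside the span of a protein-coding gene. In the mm9 list with every annotated transcript, 29.0% of summits were proximal, 32.5% intronic, 1.03% in coding exons, 1.39% in untranslated exons and 36.0% between genes.

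The palindromic E-box CACGTG, the known USF recognition site, lay within 50 bp of the summit at 5658 of 10624 mm9 peaks (53.3%, 52.3 to 54.2). Windows 500 bp away held it in 1.44%, a 37.1-fold difference. CACGTG was present at the summit and absent upstream in 5576 peaks, and the reverse held in 71 (exact McNemar test, p = 0 at machine precision). The copy nearest the summit lay at a median offset of -0.5 bp, with 91.9% of such copies within 25 bp. A further 3198 peaks (30.1%, 29.2 to 31.0) had the related E-box CACATG and no CACGTG, against 6.91% of control windows. The remaining 1768 peaks (16.6%, 15.9 to 17.4) had neither. Median signal was 75.5 with CACGTG, 57.2 with CACATG alone and 47.1 with neither.

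Stronger peaks carried CACGTG more often. The share fell from 72.1% (70.1 to 74.0) in the strongest of 5 signal bins to 42.3% (40.2 to 44.4) in the weakest, a gap of 29.8 percentage points (permutation test, p = 1.0e-05, the smallest that 100000 permutations can give). Among proximal peaks the share fell from 88.2% (85.4 to 90.5) to 27.3% (23.9 to 30.9), and among distal peaks from 60.4% (57.9 to 62.8) to 46.8% (44.2 to 49.3). Pooled over all strengths, proximal peaks had CACGTG in 56.7% (55.0 to 58.5) and distal peaks in 51.8% (50.7 to 53.0). This gap of 4.87 points had an odds ratio of 1.22 (Fisher's exact test, p = 5.0e-06), and it did not hold at all strengths. In the strongest 50% of peaks it was 14.6 points. In the weakest 50% it reversed, with CACGTG in 33.7% (31.0 to 36.5) of proximal and 48.7% (47.2 to 50.3) of distal peaks (Fisher's exact test, p = 8.1e-20).

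**Figure D2:**
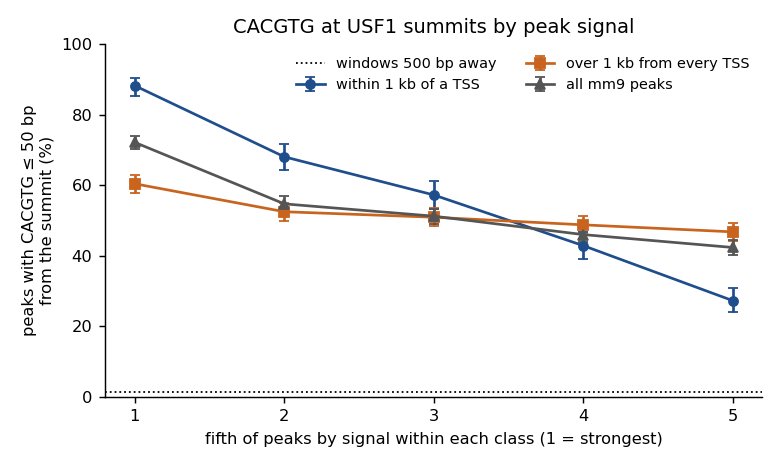
Share of mm9 peaks with CACGTG within 50 bp of the summit (y axis, percent) in 5 equal bins of signal within each class, strongest first (x axis), with 95% Wilson intervals as bars and the control windows as a dotted line at 1.44%. Proximal peaks fell from 88.2% to 27.3%, and distal peaks from 60.4% to 46.8%.

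CACATG and CACGTG differed in where they were bound. Peaks with CACATG and no CACGTG made up 37.3% (36.2 to 38.4) of distal and 12.4% (11.3 to 13.6) of proximal peaks, with an odds ratio of 0.238 (Fisher's exact test, p = 4.9e-158). Of these CACATG peaks, 41.7% lay in introns and 44.3% between genes. Peaks with neither site went the other way and made up 30.9% of proximal and 10.8% of distal peaks, with an odds ratio of 3.67 (Fisher's exact test, p = 1.5e-128). Of the peaks with neither site, 53.8% (51.5 to 56.1) were proximal, against 30.9% (29.7 to 32.1) of CACGTG peaks.

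The bases next to the core differed between bound copies and CACGTG copies nearby. TCACGTGA made up 24.4% (23.3 to 25.6) of the copies nearest summits and 5.10% of copies 250 to 1000 bp away, a 4.79-fold difference (Fisher's exact test, adjusted p = 2.7e-115). CCACGTGA was the most frequent form at summits, with 27.8% (26.6 to 28.9) against 12.5%. Forms with A before the core and C or T after it were scarce. ACACGTGC made up 1.82% at summits against 12.2% away from them, and ACACGTGT 1.13% against 7.79%. Of the other forms, ACACGTGG, CCACGTGC and GCACGTGC were lower at summits, while CCACGTGG, ACACGTGA and GCACGTGA had no detectable difference. In the strongest 50% of peaks GCACGTGA was higher at summits, with 10.3% against 7.86% (Fisher's exact test, adjusted p = 0.0151). TCACGTGA was a larger part of distal copies (27.04%, 25.7 to 28.5) than of proximal ones (18.6%, 16.8 to 20.4). Median signal was 99.7 at CCACGTGA, 90.9 at GCACGTGA, 72.1 at TCACGTGA and 49.6 at ACACGTGC.

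**Figure D3:**
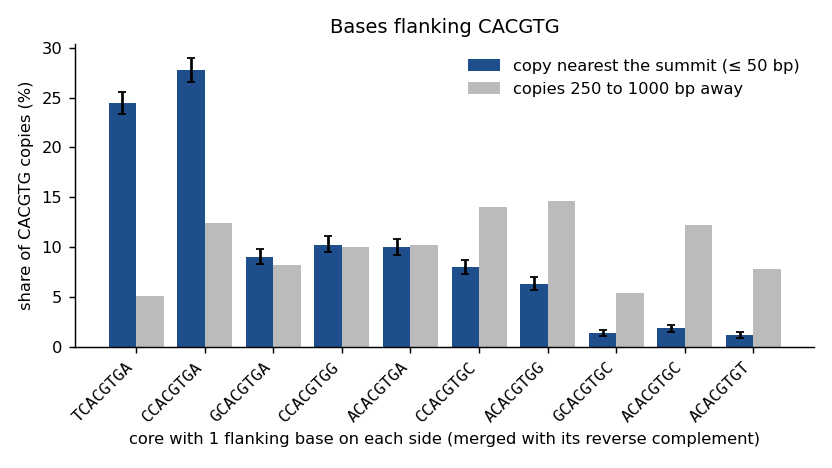
Share of CACGTG copies with each of the 10 pairs of flanking bases (y axis, percent), at the copy nearest the summit (blue, with 95% Wilson intervals) and at copies 250 to 1000 bp away (grey). TCACGTGA stood at 24.4% against 5.10%, and ACACGTGC at 1.82% against 12.2%.

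A ranking of all 2080 hexamers, which did not presuppose the E-box, placed CACGTG at rank 1 with a log2 ratio of 5.21 over control windows. The next were ACGTGA at 4.65 and CGTGAC at 4.49, which overlap the extended site. CACATG ranked 12 at 2.33. Among peaks without CACGTG, ATGTGA led at 3.34 and CACATG followed at 3.24, present in 64.4% of those peaks. Fisher's exact p was 0 at machine precision for these hexamers.

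Sites of other factors were also more frequent at USF1 summits, at 19 of the 20 fixed motif strings, counting the E-boxes themselves. The cAMP response element TGACGTCA was 8.45-fold more frequent (0.875% against 0.104%, adjusted exact p = 2.0e-25). The ETS site was 4.26-fold more frequent and stood in 8.27% of proximal and 1.39% of distal peaks, with 1.75% and 0.404% in their control windows. The SP/KLF site, a GC box of CpG-rich promoters, stood in 34.7% of proximal and 4.42% of distal peaks, with 11.7% and 1.98% in their controls. The AP-1 site was 3.44-fold more frequent and leaned the other way, with 2.43% of proximal and 7.23% of distal peaks (adjusted exact p = 3.4e-24), where controls had 1.35% and 1.84%. Sites of the B-cell factors PU.1 and octamer proteins were 2.91-fold and 2.10-fold more frequent. PU.1 stood in 1.04% of proximal and 2.16% of distal peaks (adjusted exact p = 6.9e-05), with 0.552% and 0.663% in controls. The octamer stood in 0.552% and 1.22% (adjusted exact p = 0.00172), and its controls differed in a similar proportion, with 0.308% and 0.564%. The IRF string was the exception, in 1.15% of summits and 1.29% of controls (adjusted exact p = 0.308).

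Genes of the lysosome and its acidification stood out among bound promoters. Of 20560 protein-coding genes, 2367 (11.5%) were bound. The vacuolar ATPase, which acidifies lysosomes, had 14 of 16 genes bound (87.5%, 64.0 to 96.5, adjusted exact p = 7.0e-11), led by Atp6v1c1 at a signal of 571, Atp6v0b at 544, Atp6v1h at 534 and Atp6v0d1 at 480. Of the lysosomal genes, 23 of 32 were bound (71.9%, 54.6 to 84.4, adjusted exact p = 4.8e-14), among them Naglu at 605, Mcoln1 at 582 and Ctsa at 543. These encode a heparan sulfate hydrolase, a lysosomal ion channel and cathepsin A. Autophagy genes were bound at 13 of 27 (48.1%, adjusted exact p = 1.8e-05), with Vps33a at 595, Vps11 at 565, Atg3 at 552 and Gabarap at 531. The odds ratio was 54.1 for the vacuolar ATPase, 19.8 for the lysosome and 7.17 for autophagy. That of the vacuolar ATPase, with 16 genes, varied with the setting and was 33.4 without replicate 2, 35.9 in the conservative list, 25.997 in the mm9 list with every transcript and 109 without chromosomes 3, 11 and 16.

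Binding was also frequent at ER stress genes, with 9 of 19 bound (47.4%, adjusted exact p = 5.8e-04), among them the chaperone gene Calr at a signal of 575, the stress regulator Atf4 at 486, Dnajb9 at 444 and Canx at 266. Of genes described as USF targets, 7 of 16 were bound (43.8%, adjusted exact p = 0.00355), with Cdk4 at 560, the haem oxygenase gene Hmox1 at 488, Igf2r at 463 and Trp53 at 269. Circadian clock genes were bound at 9 of 22 (40.9%, adjusted exact p = 0.00179), including the repressors Cry1 at 399 and Per1 at 358, and Tef at 303 and Nr1d2 at 234. These 3 lists and the vacuolar ATPase, lysosome and autophagy lists also passed against random lists matched on promoter CpG, with adjusted permutation p from 0.00210 to 0.0342.

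B-cell identity genes were bound at 8 of 31 (25.8%, 13.7 to 43.2, adjusted exact p = 0.0405), among them the germinal centre regulator Bcl6 at 395, the adaptor gene Blnk at 384, Ms4a1, which encodes CD20, at 382, and Spib at 175. Matched on CpG, the list passed with an adjusted permutation p of 0.0109. Its adjusted exact p rose to 0.153 without replicate 1, 0.139 in the conservative list, 0.0634 at 500 bp and 0.0880 without chromosomes 3, 11 and 16. The list still passed without replicate 2 (adjusted exact p = 0.0454), within 5 kb (45.2%, 6.9e-04) and in the mm9 list with every transcript (35.5%, 0.00717). Markers of liver (0 of 19) and neurons (0 of 17) had no bound promoter, which allows shares of up to 16.8% and 18.4% by the Wilson interval. The neuron share was 5.88% within 5 kb and 11.8% in the mm9 list with every transcript, while that of liver stayed at 0%. T-cell markers had 3 of 19, namely Cd2 at 106, Cd28 at 60.7 and Cd3d at 33.5. Antigen presentation genes had 2 of 18, Tapbp at 83.3 and Cd74 at 42.0. The T-cell, liver, neuron and antigen presentation lists did not pass the test, but within 5 kb of the TSS the T-cell list did (42.1%, adjusted exact p = 0.0121). Gene lists were not matched on expression or open chromatin in these cells, so their part in the differences between lists is unknown.

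Other growth-related lists passed the test against all genes and not against CpG-matched lists. Cell cycle genes were bound at 11 of 33 (33.3%, adjusted exact p = 0.00278, CpG-matched 0.0793), with Cdk4 at 560, the replication licensing genes Mcm2 at 480 and Mcm7 at 338, and Trp53 at 269. Nucleotide synthesis genes were bound at 8 of 26 (30.8%, adjusted exact p = 0.0148, CpG-matched 0.203), with Shmt1 at 497, Atic at 487, Nme1 at 473 and Tyms at 242. Cytosolic ribosome genes were bound at 18 of 78 (23.1%, adjusted exact p = 0.00844, CpG-matched 0.556), among them Rpl23 at 551, Rpl13a at 377 and Rps28 at 347. The ribosome list had an adjusted exact p of 0.0849 without replicate 2, 0.135 in the conservative list and 0.0627 without chromosomes 3, 11 and 16, and the nucleotide list had 0.0753 at 500 bp and 0.0880 without those chromosomes. Promoter CpG content went with binding in general, since 0.789% of genes in the lowest decile of CpG observed over expected were bound and 20.1% in the highest.

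The bHLH-ZIP family, to which USF1 belongs, had 8 of 21 genes bound (38.1%, 20.8 to 59.1, adjusted exact p = 0.00408, CpG-matched 0.0985). The bound members were Mlx at a signal of 529, the Myc partner Max at 411, Mnt at 170, Mxd4 at 131, Mlxip at 126, Mxd3 at 90.3, Usf2 at 89.4 and Mitf at 75.01. No optimal summit lay within 1 kb of the TSS of Usf1 itself, Usf3, Myc, Mycn, Mxd1, Mxi1, Mga, Mlxipl, Srebf1, Srebf2, Tfe3, Tfeb or Tfec. Srebf1 did have a weak mm9 promoter peak, with a signal of 33.7. An optimal site at 581, stronger than that of Mlx, lay inside Srebf1, 1281 bp from its 5′ end and so beyond the 1 kb limit.

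The remaining lists, of metabolism and housekeeping, did not pass the test against all genes. Lipid synthesis genes were bound at 5 of 22 (adjusted exact p = 0.176), led by Insig1 at 448, Scap at 167, Fdps at 117 and Acaca at 62.1. Glycolysis had 3 of 18, which were Eno2 at 125, Tpi1 at 73.6 and Hk2 at 73.4, and redox defence had 3 of 18, which were Hmox1 at 488, Ftl1 at 118 and Prdx1 at 47.6. The adjusted exact p was 0.525 for each of these. Without replicate 2 the glycolysis share was 27.8% against 16.7%, and the list did not pass (adjusted exact p = 0.0849). Within 5 kb of the TSS, the lipid synthesis and redox defence lists passed, each with an adjusted exact p of 0.0277. Mitochondrial ribosome genes were bound at 12 of 73, with Mrpl27 at 548 and Mrpl2 at 435, and oxidative phosphorylation genes at 12 of 75, with Ndufa7 at 347 and Atp5g1 at 319 (adjusted exact p = 0.289 for each). The region at Ndufa7 is the same as the one given for Rps28, since both starts lie within 1 kb of it. Proteasome genes were bound at 4 of 34, namely Psmb3 at 387, Psmd9 at 352, Psma4 at 204 and Psma7 at 71.6 (adjusted exact p = 1). In the mm9 list with every transcript, 44.4% of glycolysis genes (adjusted exact p = 0.00637), 31.8% of lipid synthesis genes (0.0442) and 38.9% of redox defence genes (0.0176) were bound and those lists passed. Over all 21 lists, 11 passed as higher than other genes and 0 as lower.

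**Figure D4:**
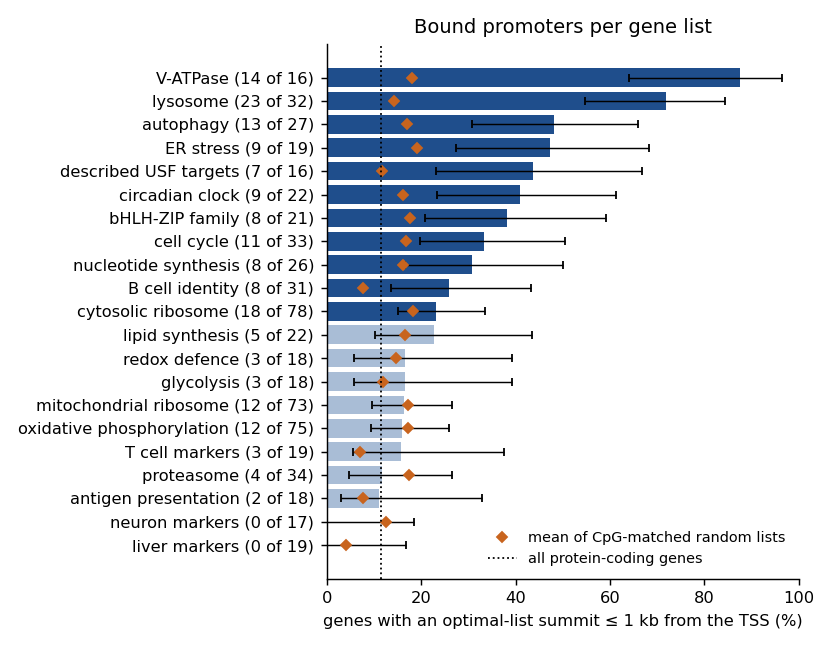
Share of genes in each list with an optimal summit within 1 kb of the TSS (x axis, percent; bars with 95% Wilson intervals, dark where the list passed the test), the mean of CpG-matched random lists (diamonds) and all protein-coding genes (dotted line, 11.5%). The vacuolar ATPase at 87.5% and the lysosome at 71.9% lie furthest from their matched means of 18.0% and 14.3%.

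The strongest promoter site was that of Eif4g1, which encodes a scaffold of translation initiation. Its mm10 region on chromosome 16, from 20672547 to 20672885, had a signal of 640 and its summit lay 14 bp from the TSS. Aldh3a2, a fatty aldehyde dehydrogenase gene, followed with a region on chromosome 11 from 61267075 to 61267364 at a signal of 637. The next were Rspry1 (chromosome 8, 94601720 to 94602002) at 624, the dynein regulator gene Ndel1 (chromosome 11, 68853066 to 68853360) at 619 and the spindle assembly gene Zfp207 (chromosome 11, 80383126 to 80383389) at 614. The lysosomal gene Naglu (chromosome 11, 101069870 to 101070156) was also among the 25 strongest, with its summit 79 bp from the TSS. So were Nagpa (chromosome 16, 5203844 to 5204166) at 589, whose product takes part in tagging lysosomal enzymes, and the vesicle tethering gene Vps33a (chromosome 5, 123572868 to 123573182) at 595.

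Others of the 25 were Rcbtb1, Marchf8, Snrpa, Fam118b, Osbpl8, Dhx35, Rmc1, Wdr19, Mtdh, Nsmce2, Klhl28, Anxa6, Ubxn1, Crebrf, Morc2a and Pkn2. The lowest signal among the 25 was 587, and the median distance of their summits to the TSS was 51 bp. In the mm9 list, 24 of the 25 genes had a promoter peak, and each of these carried CACGTG within 50 bp of the summit. For Klhl28 no mm9 peak was found within 1 kb of an annotated start of the gene. Whether both annotations place its start alike was not tested. Of the 25, 10 lie on chromosomes 3, 11 and 16, where relaxed regions were denser than on the other autosomes. The mm9 site at Zfp207 was GTCACGTGAC at positions 80196753 to 80196762 of chromosome 11. The order among the strongest sites was loose. Ranked by replicate 2 alone, 16 of these genes were among its 25 strongest promoters, and by replicate 1 alone 17 were. All 25 were among the 100 strongest in each replicate. In the mm9 list with every transcript, 6 were among the 25 strongest and 20 among the 100 strongest.

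The strongest distal site lay 4923 bp from the TSS of Slfn14, on chromosome 11 of mm10 from 83291517 to 83291782, with a signal of 616. A site at 605 lay 34843 bp from Yy1 on chromosome 12 (108757977 to 108758246), and another at 578 lay 27299 bp from B4galt5 on chromosome 2 (167376353 to 167376614). The site at 581 near Srebf1, a regulator of lipid synthesis and itself a bHLH-ZIP gene, lay inside that gene, 1281 bp from its annotated 5′ end, on chromosome 11 (60222784 to 60223039). The sites nearest the TSSs of Sgo1, Cacnb1, Kdm4c, Tnrc6c and Armt1 lay inside the spans of Sgo1, Rpl19, Kdm4c and Tnrc6c, and for Armt1 inside those of both Rmnd1 and Armt1. In mm9, where every transcript start was used, a peak with CACGTG lay 42 bp from a start of Sgo1, 7 bp from one of Rpl19, 122 bp from one of Kdm4c, 116 bp from one of Tnrc6c and 21 bp from one of Rmnd1. Weak mm9 peaks without CACGTG lay 59 bp from a start of Srebf1, with CACATG and a signal of 33.7, and 207 bp from one of Yy1, with neither site and a signal of 32.3. Whether these are the same sites was not tested, since positions were not converted between builds. Distal in mm10 is relative to a single 5′ end per gene, so a site at another start of a gene counts as distal. The mm9 signals at Srebf1 and Yy1 lay near the lowest of that list, 29.0, while the mm10 sites ranked 38 and 11 in the optimal list. The last of the 10, at 596, lay 37417 bp from H3f3a and 129 bp from an end of Sde2, a gene left without a strand.

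The mm9 and mm10 lists were spread over chromosomes in similar shares. The mm9 list had 10624 peaks, and the optimal list 8108. Chromosome 11 held the largest part of each, 11.2% of mm9 peaks and 11.1% of optimal regions, and chromosome X held 1.23% and 1.26%. Chromosome 11 had 7.60 optimal regions per Mb, against a median of 3.07 (2.496 to 4.73) over 16 other autosomes. It is also rich in genes, at 13.3 per Mb, and per gene it had 0.573 optimal regions against a median of 0.399 (0.226 to 0.509). The 16 leave out chromosomes 3 and 16, which had 0.449 and 0.591 per gene. Positions were not converted between builds, so single peaks were not paired across them.

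**Figure D5:**
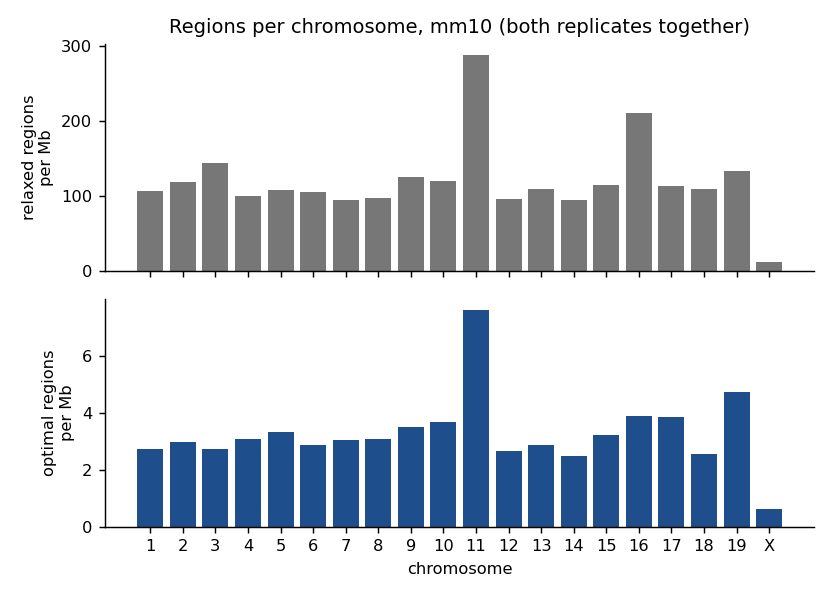
Regions per Mb of each chromosome (y axes) in mm10, for the relaxed list from both replicates (top) and the optimal list (bottom). Chromosome 11 stands at 288 relaxed and 7.60 optimal regions per Mb, and chromosome X at 12.4 and 0.611.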

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

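The tests of extra chromosome copies and of gene density on chromosomes 16 and 3 were chosen after their results had been seen, and the test of gene density on chromosome 11 was written before its result. That test had been written for the pattern on all 3 chromosomes and was narrowed to chromosome 11 afterwards. The test on chromosome 3 replaced the same test, which had decided nothing there.

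The relaxed list of both replicates, of peaks and background, appears above only by its size, signal, scores and density per chromosome. It held 288 regions per Mb on chromosome 11, 211 on chromosome 16 and 145 on chromosome 3. These stood out because they exceed every value of the 16 other autosomes, which had a median of 108.5 and ran from 94.7 to 134; chromosome X had 12.4. Each replicate showed the excess on chromosomes 11 and 16, at 28.3 and 16.4 per Mb in replicate 1 against 7.15 to 13.5 on the other autosomes, and at 49.4 and 28.8 in replicate 2 against 12.2 to 22.0. On chromosome 3 the replicates had 11.2 and 18.9 per Mb, inside those ranges. CACGTG was at 49.5% of mm9 summits on chromosome 11, 45.8% on chromosome 16 and 54.5% on chromosome 3, against 54.2% (53.1 to 55.2) elsewhere; the 3 together had 49.9% (Fisher's exact test, p = 3.8e-04), and none was tested singly. The tables argue against gene density as the whole cause. On chromosomes 11 and 16 the median count in 1-Mb bins without a protein-coding TSS was 67 and 86, or 2.68 and 3.44 times the median of 25 on the other autosomes. On chromosome 3 that median was 38.5, or 1.54 times, inside their range of 18 to 43 and so undecided, but its 5-Mb segments together held 1.44 times the count expected from segments with as many genes, where the 16 other autosomes ran from 0.764 to 1.20.

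Extra copies of chromosomes or long segments in this cell line are a candidate explanation that stays open, since 20 of 23 segments of 5 Mb on chromosome 11 (87.0%) lay above the 95th percentile of the other autosomes. The excess covered 12 of 19 segments on chromosome 16 and 5 of 31 on chromosome 3, which all lay from 133 Mb onward. These segment counts were not matched on genes. Against segments with as many genes, chromosome 11 held 2.33 times the expected count, where the 16 other autosomes ran from 0.764 to 1.20. The low density of chromosome X, 12.4 per Mb in a line labelled female, was not weighed against extra copies. Control libraries were not used here, and no biological explanation in terms of USF1 binding was tested.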

How the results depend on the processing

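The mm9 annotation, the strongest and weakest 50% of the mm9 list, leaving out chromosomes 3, 11 and 16, all shared replicate 1 regions, bins of signal for promoter odds, and the alternatives for named genes were chosen after the results were seen; the others were planned. Of 47 alternatives to the main results, 36 kept the direction and the side of the threshold, the value within its spread, or a count within a fixed tolerance. A further 9 moved beyond these. The last 2 changed direction. In 1 the gap in CACGTG shares reversed, and in the other the promoter odds ratio only fell to 0.998, where no difference was detected. The share of optimal regions found in both replicates (99.3%) became 99.9% in the conservative list, 91.9% with a reciprocal overlap of 50% and 97.9% with summits within 100 bp. The last pair follow from stricter matching; for the conservative list the cause was not tested. The rank correlation of signal (0.874) became 0.920 in the conservative list, 0.830 over all replicate 1 regions found in replicate 2 and 0.915 as Pearson's r on log2 signal, and the cause was not tested. The promoter odds ratio of shared over other optimal regions (1.74) became 0.998 within bins of signal, which narrow the difference in strength. The signal of shared and other regions was not compared within bins. The count of gene lists past the threshold was 11; it was 7 against CpG-matched random lists and ran from 8 to 14 in the other alternatives. Of the 25 strongest promoters, 16 to 17 were among the 25 strongest when ranked by a single replicate and 6 in the mm9 list with every transcript; the cause was not tested. The proximal share ran from 23.4% to 38.8% over distances of 500 bp and 5 kb, and the CACGTG share from 47.5% to 61.0%. The gap between proximal and distal CACGTG shares reversed from 4.87 to -15.0 points in the weakest 50% of the mm9 list, and the cause was not tested; otherwise it ran from 3.44 to 14.6 points. For the single gene lists, 149 of 168 alternatives kept the call, 13 lost it, 6 gained it and 0 reversed. The lists of the vacuolar ATPase, lysosome, autophagy, ER stress, circadian clock and described USF targets passed in all 8 alternatives run for them. Sequence results could not be repeated in the conservative list or without a replicate, and CACGTG was not compared between conservative and optimal regions, because no mm10 sequence was used here. No paired analysis was possible because the series has 1 group. Read depth is unknown, so the longer list of replicate 2 cannot be set against its depth.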

Other observations

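The tests of site availability and of weak optimal regions were chosen after their results were seen, as were the single genes named in this part; the test of peak strength was written before its result.

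Genomic copies of the USF sites were occupied to different degrees. Of 262836 CACGTG copies in the mm9 genome, 2.29% (2.23 to 2.35) lay within 50 bp of a summit, with 19.3% (18.6 to 20.1) of promoter copies and 1.63% (1.58 to 1.68) of distal ones. For the extended site TCACGTGA these shares were 10.9% (10.4 to 11.5), 54.0% (50.2 to 57.7) at promoters and 8.67% (8.20 to 9.18) elsewhere. CACATG, with 2458384 copies, was occupied at 0.185%, with 1.31% (1.20 to 1.42) of promoter copies and 0.166% (0.161 to 0.172) of distal ones. TCACATGA was occupied at 1.36%, with 8.19% (7.07 to 9.47) and 1.26% (1.20 to 1.32). Each form thus lay near a summit at a higher share in promoters, including CACATG, although most of its occupied copies, 4026 of 4538, were distal. Summits were themselves denser there, since 29.0% of mm9 summits were proximal against 2.53% of random positions. No chance level was taken off these shares, so the rise at promoters is not shown to be particular to these sites. Peaks with 1 copy of CACGTG in the window had a median signal of 74.3, the 258 peaks with 2 copies had 109, and the 30 peaks with 3 or more had 86.7.

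Some strong promoter peaks in mm9 lacked CACGTG. The promoter peaks of Commd4 (ATCACATGAC), Mff, which encodes a mitochondrial fission factor (GTCACATGAC), and the lysosomal peptidase gene Tpp1 (GTCACATGAG) carried CACATG in an extended site, with signals of 2565, 2535 and 1968. Mfsd11, at 4957, and Dnajc16, at 2318, had neither site within 50 bp of the summit. Among all 1768 peaks with neither site, the top hexamer was CGTGAC, which shares its bases with one side of the extended site, at a log2 ratio of 3.67 and 20.1% of windows. CACGCG stood in 15.7% against 2.26% of controls, CACCTG in 33.5% against 7.44%, and the ETS string in 7.98% against 1.13%.

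Of the peaks with CACATG and no CACGTG, 11.98% were proximal, above the 2.53% of random positions for the mm9 list. Relative to other USF1 peaks they lay away from promoters, with the odds ratio of 0.238 given above. The tables argue against peak strength as the cause, since the odds ratio lay between 0.223 and 0.339 in each of the 5 signal bins. A scarcity of CACATG at promoters may contribute, because promoters held 4.02 copies of CACATG per CACGTG and distal sequence 9.56. Occupied shares rose from distal to promoter sequence 1.51 (1.36 to 1.68) times more for CACGTG than for CACATG, and 0.957 (0.800 to 1.14) times for the extended forms. The first interval lies above 1 and includes the bound of 1.5, which was set after the results were seen. For the core forms, copies (2.38 times) and occupied shares thus both differed. For the extended forms no difference in occupied shares was detected. How much of the pattern each accounts for was not tested. Because no chance level was taken off the occupied shares, the ratios of those shares also count copies near summits by chance. No biological explanation was tested.

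The optimal list held 50 regions with a column 9 score below 0 and a median signal of 8.14. Their median rank in the relaxed list of both replicates was 94300. A second region called on the edge of a stronger one may account for them. Of the 50, 100% (92.9 to 100) had a stronger relaxed region within 500 bp, against 3.58% of 5000 sampled relaxed regions. The share was 0.769% in the other optimal regions, but the optimal list had a median signal of 72.25, which leaves fewer stronger regions to find. Summits of the 50 lay a median of 204 bp and 178 bp from the nearest summit of replicates 1 and 2. For the other optimal regions these distances were 6 bp and 5 bp. The conservative list held 44 regions with a column 9 score below 0.

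The mm9 list held 1 peak on chromosome Y, from 582111 to 582335, 15 bp from the TSS of Uty, with a signal of 377 and CACGTG. The labels give the line as female, and the mm10 lists used here held no region on that chromosome.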
